A study of Mus musculus with 5 samples.

How the data were processed

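Total RNA of whole thymus was labelled in 2 colours and hybridised to Agilent mouse arrays, per the labels. The series design text gives 60-base oligonucleotide probes. The 5 arrays each held ZAS3-null RNA in channel 1 and wild-type RNA in channel 2, per the labels. Per the series design text, images were read with GenePix, data were analysed in GeneTraffic 2.6, and lowess normalization was applied to each array. The same text says that spots dimmer than their background or with a raw intensity under 100 were left out of that normalization. The deposited values are log2 ratios of the 2 channels, 1 column per array, made by the authors. The log base was settled from the values: within 6e-05, 100% of them were the log2 of a fold of at least 1 with 2 decimals, with its sign, against 8.0% for log10. Scanner files, spot brightness and spot flags were not analysed here, so dim spots could not be left out. The median log2 ratios of arrays 1 to 5 were 0, -0.08, -0.01, 0 and 0. No 2 arrays held identical values.

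The probe numbers of the value table did not pair its values with the right genes of the platform annotation, and a different order was recovered from the data. The values follow a grid of 215 rows and 105 columns, and the annotation's numbers follow the same slide with rows and columns exchanged about a diagonal. Under the numbers as deposited, 41 of 256 spots that lay below -1.5 on every array fell on numbers with no gene, and probes of the same gene correlated at 0.01 across 1666 pairs. With the exchanged order, 256 of 256 fell on numbers with no gene, which are 19.2% of all numbers. Probes of the same gene then correlated at 0.36 across 1714 pairs, and at 0.28 after position correction. In 1000 random orders that value ranged from -0.06 to 0.07. For 48 genes with at least 10 spots, the median SD between spots of a gene was 0.09 to 0.11 on arrays 2 to 5 with the exchanged order and 0.23 to 0.45 with the deposited numbers. On array 1 it was 0.26 against 0.35, and 0.26 still exceeded the SD of 0.23 between gene means. All gene names rest on the exchanged order, which was chosen after seeing the data, and the names by deposited numbers were run as an alternative. The annotation gave 1 gene for 18218 probes, several for 16 and none for 4341. Of the probes with 1 gene, 18175 matched the reference gene table by gene number, and 0 symbols had to be updated. Probes of a gene were averaged on each array (1193 genes had several), and unnamed probes stayed single, which gave 20861 features.

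Each feature was tested against 0 with an intercept-only limma fit and moderated statistics (limma 3.58.1 in R 4.3.3), with Benjamini-Hochberg adjustment over all 20861 features and a threshold of 0.05. The ratios were not centred or scaled further. Separate mice are named for each array, so p-values measure the spread between pairs of animals together with technical spread. The arrays had no dye swap, so the dye effect stays in every value. Values are mean ± SD over 5 arrays. The rule of the design text, a fold of 1.5 on at least 4 arrays in one direction, was counted without a test. Gene lists were tested with cameraPR at a preset correlation of 0.01 over the 39 of 41 lists with at least 5 genes measured, beside camera with an estimated correlation. Both compare a list with all other features, unnamed ones and the 256 very low spots among them. The lists were also tested with fry, which compares a list with no change and not with other features. As deposited, 0 lists passed with either correlation, and after position correction the cell cycle list passed with the preset one alone. The lists, the tests and the rule for named genes were fixed before the data were examined.

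The named genes were Hivep1, Hivep2 and Hivep3, and the 12 largest positive and 12 largest negative means among genes past the threshold with the same sign on every array. From each list with a shift past the threshold up to 4 members were taken. From the thymocyte, NF-kB, AP-1 and tumour necrosis factor lists the 4 members with the smallest p were taken whether or not they passed. The same rule was applied to the position-corrected values, which was decided after seeing the data. That gave 78 genes in all.

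For the position correction, the median of the surrounding 21 by 21 spots of the same array was subtracted from each log2 ratio, leaving out the 256 very low spots. It was added after seeing the data. A second form subtracted column and row medians. Other alternatives were median centring, scaling of the arrays to a common spread, single probes, each array left out in turn, robust eBayes, array weights, other thresholds, and ranks or an estimated correlation for the lists. No value was missing, so asking for 3 or for all 5 arrays with a value gives the same fit.

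The steps were tested on simulated data. On a simulated slide of 22575 spots with a trend of 0.5 across the columns, the right order was found, the fitted trend went from 0.51 to 0.01, and a shift of 1 kept a mean of 0.99. With 20861 features and 5 arrays, limma recovered 0% of features changed by 0.3, 41.8% of those changed by 0.6 and 78.8% of those changed by 1 on the log2 scale, and 3.61% of the calls were unchanged features. That simulation had independent spread between features and no trend or dye effect shared by the arrays. Its shares therefore do not carry over to the deposited ratios. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.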

Results

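Gene expression was compared between the thymus of mice without ZAS3 and the thymus of wild-type mice. ZAS3, the product of Hivep3, is a large zinc finger protein that binds kappaB-like DNA sequences and takes part in NF-kB and AP-1 signalling. The thymus is the organ in which T cells develop, and most of its cells are immature T cells (thymocytes). The animals were littermates of 6 to 8 weeks, matched for sex and age. Each of 5 arrays paired RNA of one ZAS3-null thymus with RNA of one wild-type thymus, so there was 1 group of 5 replicates and no array of 2 samples of the same genotype. The table held a log2 ratio for each of 22575 spots on each array, with 0 missing values, and 16504 genes could be named. Spot brightness was not part of the table, so the number of arrays sets the precision. The sample labels speak of whole thymus and the design text of thymocytes.

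The direction of the ratios was not settled by the sources. The sample labels place the ZAS3-null RNA in the Cy5 channel and the design text places it in Cy3. A positive log2 ratio likely stands for a higher level in the ZAS3-null thymus, on the basis of the sample titles and the order of the channels. Values are therefore given as positive or negative log2 ratios. Dye and genotype ran together on all 5 arrays, so a dye effect on a probe cannot be separated from an effect of the genotype.

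The targeted gene, Hivep3, had a mean log2 ratio of 0.08 ± 0.07 (SD, n = 5), which did not differ from 0 (limma adjusted p = 0.37). Its values on arrays 1 to 5 were 0.07, 0.15, -0.03, 0.09 and 0.10, and its 2 probes had means of 0.14 and 0.01. With position correction its mean was 0.17 ± 0.09 (adjusted p = 0.141), positive on 5 of 5 arrays, and its probes had 0.20 and 0.14. The deleted part of the gene is not given in the labels, and a probe outside it checks nothing, so Hivep3 did not settle the direction. Of the related family members, Hivep1 had a negative log2 ratio of -0.30 ± 0.13 (adjusted p = 0.0267), and Hivep2 had -0.29 ± 0.27 (adjusted p = 0.0945). After correction for position on the slide neither passed, with means of -0.07 and -0.16. As deposited, the call of Hivep1 was lost without array 3, 4 or 5 (adjusted p up to 0.0869).

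The arrays resembled one another to different degrees. The correlation of log2 ratios across features, which are not independent replicates, ranged from 0.38 for arrays 1 and 2 to 0.86 for arrays 3 and 4, with a median of 0.66 over the 10 pairs. Part of this came from 256 spots, none of them on a named gene, that lay below -1.5 on every array. Without them the median was 0.47, with 0.14 for arrays 1 and 2. With position correction besides, the correlations ranged from 0.09 for arrays 1 and 2 to 0.64 for arrays 4 and 5, with a median of 0.46. The log2 ratios also rose across the slide on every array. In the mean of the 5 arrays the rise was 0.51 from the first to the last column (95% bootstrap interval over spots 0.49 to 0.52). That interval does not measure the spread between arrays. The median of the first 10 columns lay between -0.25 and -0.11 on the 5 arrays, and that of the last 10 columns between 0.23 and 0.31. Because this trend was shared by the arrays, each count is given for the ratios as deposited and again after the median of the surrounding 21 by 21 spots was subtracted.

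**Figure D1:**
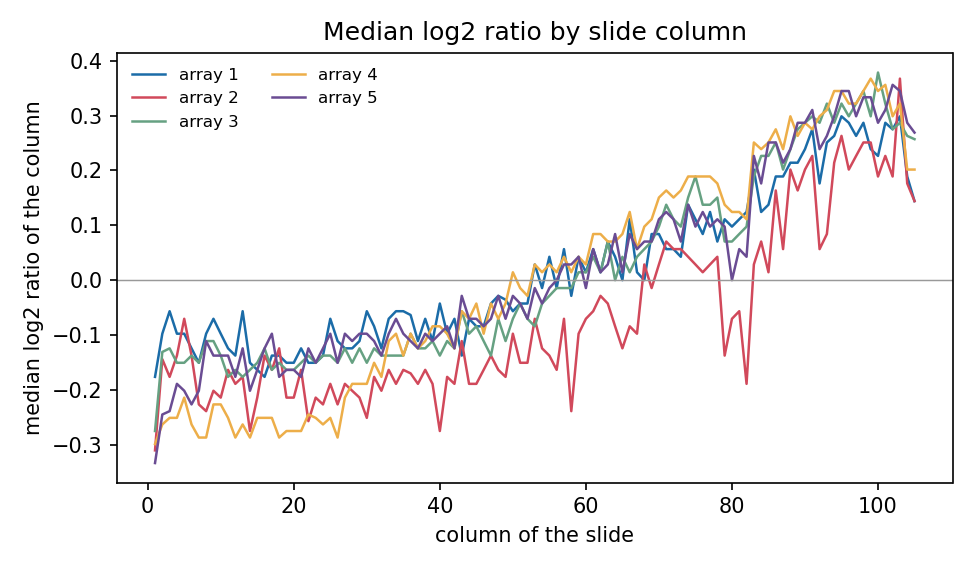
Median log2 ratio (vertical axis) of each slide column (horizontal axis), with 1 line per array and without the 256 spots that lay below -1.5 on every array. All 5 lines lie below 0 over the first 10 columns and above 0 over the last 10.

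A set of 8 named genes differed from 0 in the main fit of all arrays and in each fit with 1 array left out, before and after the position correction. Pigt, a subunit of the complex that attaches GPI anchors to proteins, had the largest positive log2 ratio, 1.47 ± 0.30 (SD, n = 5; 2.77-fold; limma adjusted p = 0.0015), and 1.60 ± 0.25 after correction. Gnai1, an inhibitory G protein subunit, had 0.51 ± 0.05 and 0.57 ± 0.07 after correction. On the negative side, Smg9, a component of nonsense-mediated mRNA decay, had -1.79 ± 0.25 (3.47-fold), and the zinc finger genes Zfp771 and Zic4 had -1.92 ± 0.54 and -1.24 ± 0.39. Efcab5 (-0.95 ± 0.11), Sec14l3 (-0.92 ± 0.26) and the hair keratin-associated gene Krtap4-7 (-0.88 ± 0.28) made up the remainder. Each of the 8 genes was measured by 1 probe. These genes, like all named genes given below as past the threshold, had the same sign on 5 of 5 arrays.

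Over all genes, 1973 of the 16504 had a positive and 2122 a negative log2 ratio past an adjusted p of 0.05. After the position correction 101 were positive and 380 negative, and 390 of these 481 genes were among the 4095 called before it, all with the same sign. The calls as deposited followed the slide. Of the genes in columns 1 to 35, 15 were called positive and 1381 negative, against 1698 and 62 in the last 35 columns. The corrected count also depended on single arrays, and was 23 without array 5, 28 without array 4, 57 without array 1, 107 without array 3 and 1152 without array 2. As deposited, the count was 734 without array 5, 1348 without array 4, 2174 without array 1, 2856 without array 3 and 4763 without array 2. Of the corrected calls, 390 were made before correction too and 91 only after it.

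The 12 largest positive ratios as deposited were those of Pigt, Elavl4, Olfr27, Otud4, Fuca1, Mif, Fcgr4, Scamp4, Olfr701, Ackr2, Vmn1r26 and Sphk1. All except Pigt lay in columns 89 to 104. As deposited, the call of Olfr701 was lost without array 2, 3, 4 or 5 (adjusted p up to 0.135). That of Otud4 was lost without array 1 or 5 (up to 0.0693), and that of Fuca1 without array 5 (0.0621). Of these 12, 5 also passed after correction: Pigt, the odorant receptor Olfr27 (0.90 ± 0.14 before and 0.59 ± 0.18 after), the Fc receptor Fcgr4 (0.75 ± 0.15 and 0.48 ± 0.19), the chemokine-scavenging receptor Ackr2 (0.74 ± 0.17 and 0.55 ± 0.20) and the pheromone receptor Vmn1r26 (0.73 ± 0.14 and 0.44 ± 0.16). Mif, a macrophage cytokine, had 0.78 ± 0.26 before and 0.47 ± 0.24 after correction (adjusted p = 0.0511). The 12 largest positive ratios of the corrected values, a set chosen after the trend was seen, added Lars2, Olfr1270, Gnai1, Foxn1, Vsx1, 1700016H13Rik, Pcdha3 and Aldh8a1. Foxn1, the transcription factor on which thymic epithelium depends, had 0.54 ± 0.11 as deposited (adjusted p = 0.0052) and 0.56 ± 0.16 after correction (adjusted p = 0.0135), positive on 5 of 5 arrays. The corrected call of Foxn1 was lost without array 1, 4 or 5 (adjusted p up to 0.075). Those of Olfr27 (up to 0.0978), Fcgr4 (0.118), Ackr2 (0.088) and Vmn1r26 (0.17) were lost without array 1, 3 or 5, and the last 3 also without array 4.

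The 12 largest negative ratios as deposited were those of Mtg1, Tmem164, Nle1, Zfp771, Mxra8, Galntl6, Smg9, Drosha, Gse1, Ppp2r5a, Nkx2-3 and Zic4. Mtg1, a GTPase of the mitochondrial ribosome, had -2.32 ± 1.12 (5.01-fold), and Nle1, a ribosome assembly factor, had -1.97 ± 1.17. Drosha, the nuclear nuclease of microRNA processing, had -1.73 ± 1.11 (adjusted p = 0.0251) and -1.75 ± 1.07 after correction (adjusted p = 0.0551). Of these 12, 8 passed after correction, but the corrected calls of Mtg1, Tmem164, Nle1, Galntl6 and Gse1 were each lost without array 1, 4 or 5 (adjusted p up to 0.138, 0.173, 0.141, 0.154 and 0.135). Array 3 held the weakest value of 11 of the 12, as for Mtg1, with -0.55 on array 3 and -1.95 to -3.24 on the others. As deposited, the calls of Mtg1, Tmem164 and Galntl6 were lost without array 5 (adjusted p up to 0.0537, 0.0589 and 0.0545). Those of Nle1, Drosha and Ppp2r5a were lost without array 1, 4 or 5 (up to 0.0699, 0.0911 and 0.0986), and those of Mxra8 and Nkx2-3 without array 1, 2, 4 or 5 (up to 0.122 and 0.14). The corrected 12 added Efcab5, Sec14l3, Padi3 and Krtap4-7.

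**Figure D2:**
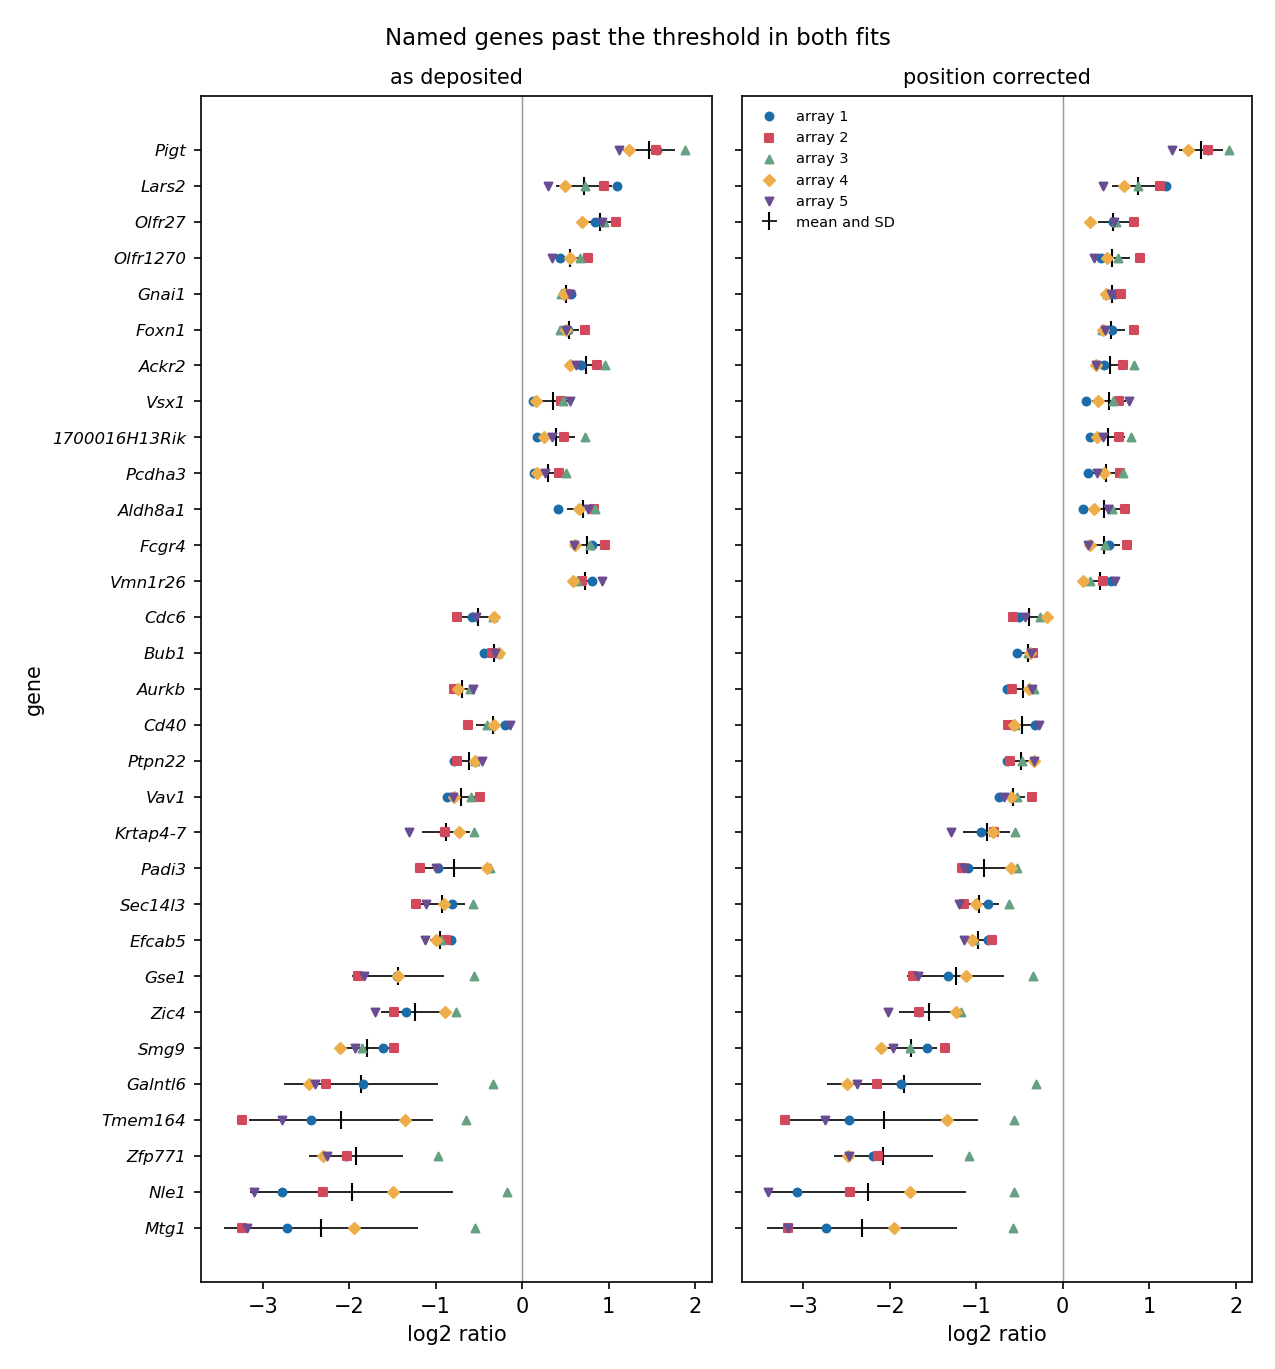
Log2 ratio (horizontal axis) of the 31 named genes past an adjusted p of 0.05 both as deposited (left) and after position correction (right), with 1 symbol per array and a bar for the mean and SD of 5 arrays. The 13 positive and 18 negative genes keep their sign on all 5 arrays in both panels.

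The rule stated in the design text asks for a change of at least 1.5-fold on at least 4 of the 5 arrays. As deposited, 67 genes met it on the positive side and 76 on the negative side. After position correction 8 and 32 did, and 27 genes met it both times. With 1 array left out and 3 of the remaining 4 required, the genes past the 1.5-fold rule numbered between 219 (without array 5) and 393 (without array 3), with 297, 326 and 310 without arrays 1, 2 and 4. The genes past the 1.5-fold rule after position correction then numbered 77, 126, 118, 144 and 45 without arrays 1 to 5. This rule gives no p-value.

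Genes of T cell receptor signalling and of CD4+CD8+ thymocytes lay below the mean of all features on arrays 1, 4 and 5 and not on arrays 2 and 3. Relative to all features, the receptor list had means as deposited of -0.22, 0.17, 0.03, -0.04 and -0.20 on arrays 1 to 5, and the CD4+CD8+ list had -0.44, 0.21, 0.02, -0.18 and -0.40. That reference included unnamed features and the 256 very low spots, which lower it. It was also lower on array 2. A value above 0 on this scale need not be a positive log2 ratio. Without the subtraction, the receptor list had a mean of -0.131 over all arrays, -0.1521 without array 2 and -0.1585 without array 3. The CD4+CD8+ list had -0.2327, -0.2902 and -0.2844. Neither list therefore had a positive mean on array 2 or 3. Of 24 genes of the receptor complex and its proximal signalling, 8 were negative and 2 positive past the threshold over all genes tested, and 9 and 3 when adjusted over the list alone. Vav1, an exchange factor that acts below the receptor, had -0.71 ± 0.16 (adjusted p = 0.0037) and -0.58 ± 0.15 after correction (adjusted p = 0.0098). The phosphatase gene Ptpn22 had -0.62 ± 0.14 and -0.48 ± 0.15 after correction, and passed both times. Both corrected calls were lost without array 4 or 5, and that of Ptpn22 also without array 1 or 3 (adjusted p up to 0.0743 and 0.0928). Lcp2 had -0.41 ± 0.10 and Cd3e 0.40 ± 0.04, and neither passed after correction. Cd3e lay in column 101 of the slide, and Vav1 and Ptpn22 in columns 21 and 14. As deposited the call of Lcp2 was lost without array 5 (adjusted p = 0.0528). The list as a whole did not differ from other features (mean -0.13; cameraPR adjusted p = 0.501, and 0.101 after correction). The corrected list passed without array 2 (mean -0.19; adjusted p = 0.02), and its adjusted p ranged from 0.018 with array weights to 0.902 with deposited numbers. Deposited numbers put other genes under these names, and the highest of the other settings was 0.434, without array 1. All these p-values use a preset correlation of 0.01, and with the estimated correlation of 0.281 the adjusted p over all arrays was 0.802.

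Of 14 genes of CD4+CD8+ thymocytes, 3 were negative past the threshold and 0 positive, with the same counts when adjusted over the list alone. These were Rag1, which cuts DNA in receptor gene rearrangement (-0.81 ± 0.37; adjusted p = 0.0122), Cd8a (-0.50 ± 0.23) and Cd4 (-0.32 ± 0.12). They lay in columns 15, 31 and 27 of the slide. After correction their means were -0.61, -0.33 and -0.19 and none of the 3 passed, while 1 other gene of the list was negative past the threshold. Bcl6 had 0.22 ± 0.13 and did not pass. The list mean was -0.23 as deposited (adjusted p = 0.501) and -0.23 after correction (adjusted p = 0.101). The corrected list passed without array 2 (mean -0.30; adjusted p = 0.008) and without array 3 (mean -0.28; 0.0473). Its adjusted p ranged from 0.008 to 0.903 over the settings of cameraPR, with the highest for deposited numbers. Those numbers put other genes under these names, and the highest of the other settings was 0.386, without array 1. All these p-values use a preset correlation of 0.01, and with the estimated correlation of 0.695 the adjusted p over all arrays was 0.802. As deposited the calls of Rag1 and Cd8a were lost without array 4 or 5 (up to 0.0579 and 0.0661), and that of Cd4 also without array 1 (up to 0.0858).

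Among genes of early thymocytes and the pre-T cell receptor, Bcl11b had -0.45 ± 0.18, while Ptcra, the invariant chain of the pre-T cell receptor, had 0.35 ± 0.11 and Lmo2 had 0.45 ± 0.20. All 3 passed as deposited and not after correction, and were lost as deposited without array 4 or 5 (adjusted p up to 0.0616, 0.0597 and 0.0655). Among genes of mature thymocytes, Tox (-0.61 ± 0.15), Cd69 (-0.56 ± 0.15) and Foxo1 (-0.37 ± 0.12) were negative and Il6ra (0.51 ± 0.08) positive as deposited. The first 3 lay in columns 9, 24 and 34 of the slide and Il6ra in column 89. After correction none of these 4 passed, with adjusted p of 0.0501 for Tox and 0.0536 for Cd69. As deposited, the call of Foxo1 was lost without array 5 (adjusted p = 0.0592). Of 10 regulatory T cell genes 0 passed with limma as deposited and 1 had an unadjusted p under 0.05, against 6655 of all 16504 genes. Foxp3, the defining transcription factor of these cells, had 0.26 ± 0.36 (adjusted p = 0.202). None of these 3 lists passed, with cameraPR adjusted p of 0.791, 0.806 and 0.791 as deposited and 0.719, 0.25 and 0.665 after correction.

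As deposited, NF-kB subunits, regulators and targets and AP-1 and immediate early genes, which bear on the known partners of ZAS3, went both ways. The signs of the members named here matched the trend across the slide. Of 27 NF-kB subunits, regulators and targets, 4 were positive and 4 negative past the threshold, and 4 and 5 when adjusted over the list alone. Relb had 0.45 ± 0.07 and the adhesion gene Icam1 0.35 ± 0.09, while the adhesion gene Vcam1 had -0.54 ± 0.17 and the kinase gene Ikbkb -0.36 ± 0.11. Relb and Icam1 lay in columns 93 and 101 of the slide, and Vcam1 and Ikbkb in columns 9 and 5. As deposited the calls of Icam1 and Ikbkb were lost without array 4 or 5 (adjusted p up to 0.0622 and 0.0655). After correction 0 of the 27 passed with limma and 8 had an unadjusted p under 0.05. Over all 16504 genes 4457 did, a similar share. Of 24 AP-1 and immediate early genes, 2 were positive and 4 negative, with Junb at 0.45 ± 0.14 and Jun at -0.46 ± 0.14. Klf6 had -0.39 ± 0.12, with both its probes negative, and Egr2 had -0.38 ± 0.15. Junb lay in column 87, Jun in column 4, Egr2 in column 11 and the 2 Klf6 probes in columns 33 and 26. After correction these 4 had 0.23, -0.29, -0.22 and -0.19 and did not pass. As deposited those of Klf6 and Egr2 were lost without array 4 or 5 (up to 0.0604 and 0.0729).

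Of 13 genes listed as AP-1 targets, Ccnd1 (0.27 ± 0.04) and Mmp9 (0.21 ± 0.03) passed as deposited, and Csf2 (0.24 ± 0.15) and S100a4 (0.27 ± 0.24) did not. After correction Ccnd1 had 0.09 (adjusted p = 0.393) and Mmp9 0.15 (0.159), and neither passed. As deposited, the call of Ccnd1 was lost without array 4 or 5 (up to 0.0807), and that of Mmp9 also without array 1 or 3 (up to 0.124). Of 18 genes of tumour necrosis factor and TRAF signalling, 4 were negative and 0 positive. These were Map2k4 (-0.43 ± 0.06), Mapk8 (-0.32 ± 0.14), Cd40 (-0.34 ± 0.19) and Fas (-0.27 ± 0.15). As deposited, the last 3 were lost without array 1, 4 or 5, and Cd40 and Fas also without array 3 (adjusted p up to 0.0845, 0.0974 and 0.128). Cd40 alone of these 4 passed after correction, at -0.47 ± 0.16 (adjusted p = 0.029), a call lost without array 1, 3, 4 or 5 (up to 0.13). None of the lists of NF-kB, AP-1, AP-1 target and tumour necrosis factor genes differed from other features, with cameraPR adjusted p of 0.916, 0.538, 0.501 and 0.538 as deposited.

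Cell cycle genes lay below the mean of all features on arrays 1, 4 and 5 and not on arrays 2 and 3. Relative to all features, the list means as deposited were -0.23, 0.04, 0.01, -0.15 and -0.18 on arrays 1 to 5. The reference again included the 256 very low spots, and it was lower on array 2. Without the subtraction, the list mean was -0.1785 over all 5 arrays, -0.1805 without array 2 and -0.2132 without array 3. The list mean was therefore negative on arrays 2 and 3 too, and weakest on array 3. Of 33 tested, 11 were negative and 2 positive past the threshold as deposited, and 11 and 3 when adjusted over the list alone. The mitotic kinase gene Aurkb had -0.69 ± 0.10 and -0.46 ± 0.15 after correction, the spindle checkpoint gene Bub1 had -0.33 ± 0.07 and -0.40 ± 0.07, and the replication licensing gene Cdc6 had -0.51 ± 0.18 and -0.39 ± 0.17. These 3 passed both times, while Bub1b had -0.43 ± 0.22 after correction (adjusted p = 0.0569). The corrected calls of the 3 were lost without array 1, 3, 4 or 5 (adjusted p up to 0.111, 0.118 and 0.204). As deposited, those of Bub1 and Cdc6 were lost without array 5 (adjusted p = 0.0617 and 0.0545). The list mean was -0.18 as deposited (adjusted p = 0.239) and -0.16 after correction, where it passed (adjusted p = 0.0359), with 3 genes negative over all and 12 when adjusted over the list alone. With an estimated correlation the corrected list had an adjusted p of 0.802. The corrected call was also lost without array 1, 4 or 5, with adjusted p of 0.198, 0.123 and 0.169. As deposited the list passed without array 3 (mean -0.21; adjusted p = 0.0306) with the preset correlation of 0.01, while with the estimated correlation of 0.201 its adjusted p over all arrays was 0.926. Over all settings of cameraPR its adjusted p ranged from 0.0306 to 0.942 as deposited and from 0.0035 to 0.975 after correction, with the highest for deposited numbers. Those numbers put other genes under these names. The highest of the other settings, without array 1, was 0.6105 as deposited and 0.198 after correction.

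No list among the 39 tested differed from other features as deposited with limma's cameraPR, where 3 had an unadjusted p under 0.05. With the rank-based form or an estimated correlation, 0 did. The other features included unnamed ones and the 256 very low spots, which lower the level a negative list must fall below. Lists were not tested against named genes alone. After correction 1 list passed with cameraPR (8 at an unadjusted p under 0.05), 8 with the rank-based form, and 0 with an estimated correlation. The corrected cameraPR count was 0 without array 1, 4 or 5, 4 without array 2 and 6 without array 3. Against no change instead of other features, fry called 0 lists in one direction before and after correction. With changes in either direction counted together it called 38 lists as deposited and 27 after correction. The 38 of 39 included skeletal or cardiac muscle genes, so that count sets no list apart. Against no change, a dye effect or a trend shared by the arrays counts as a change too. Next to cell cycle, the lowest adjusted p as deposited were those of the adipocyte list (mean 0.23; adjusted p = 0.253) and of heat shock and unfolded protein genes (mean -0.20; adjusted p = 0.253). After correction, interferon-stimulated genes (mean -0.14), genes of MHC class I and the immunoproteasome (mean -0.17) and adipocyte genes (mean 0.19) each had an adjusted p of 0.098, and ribosomal protein genes (mean -0.11) had 0.101. Oxidative phosphorylation, glycolysis, sterol synthesis, apoptosis and glucocorticoid response genes had corrected means between -0.13 and -0.06 and did not pass.

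The lists of adipocyte, lymph node stroma, erythroid and CD4+CD8+ thymocyte genes differed widely between arrays. Relative to all features, the corrected mean of the adipocyte list was 0.54 on arrays 4 and 5 and between -0.03 and 0.14 on arrays 1 to 3. That of lymph node stroma was 0.68 on array 1 and -0.10 on array 2, and that of erythroid genes was 0.67 on array 2 and -0.23 on array 5. The CD4+CD8+ thymocyte list stood at -0.44 on array 1 and -0.39 on array 5, against 0.22 on array 2. On the same scale, cortical epithelium genes had means of 0.03 to 0.36 and B cell genes of 0.11 to 0.24. The mean subtracted was lower on array 2 than on the other arrays, which raises all list values there. Without the subtraction, the cortical list stood at -0.01 on array 1, -0.02 on array 5 and 0.21 on array 2. The B cell list then ran from 0.04 on array 1 to 0.19 on array 4. Neither list passed (adjusted p = 0.536 and 0.25).

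**Figure D3:**
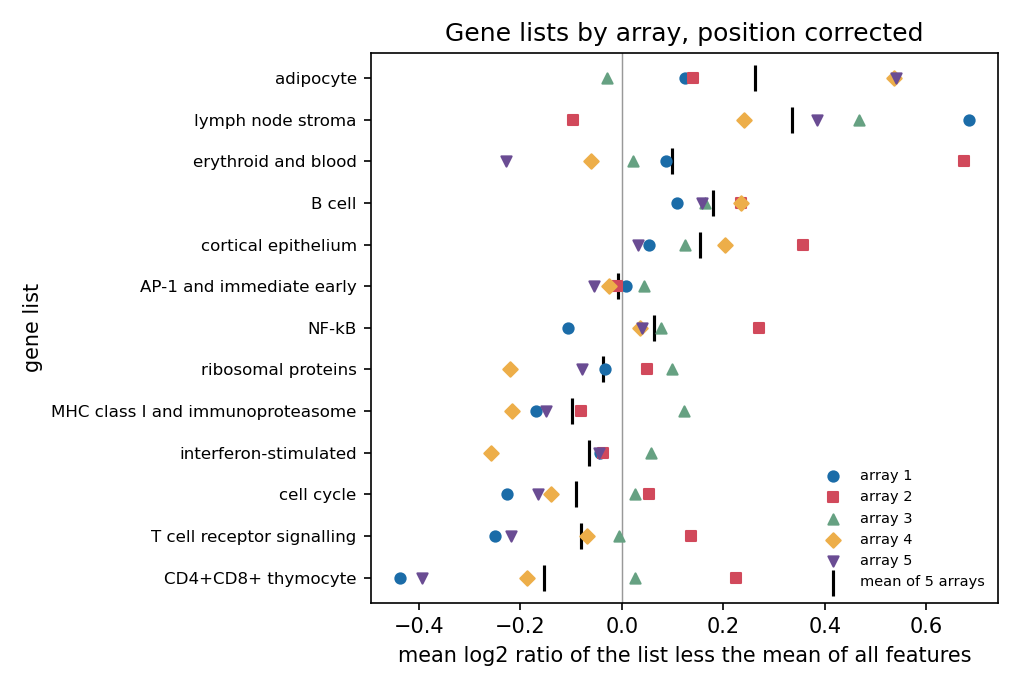
Mean log2 ratio of 13 gene lists after position correction, less the mean of all features (horizontal axis), with 1 symbol per array and a tick for the mean of the 5 arrays. The CD4+CD8+ thymocyte list runs from -0.44 on array 1 to 0.22 on array 2, and the adipocyte list stands at 0.54 on arrays 4 and 5.

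Array 2 stood apart in its spread and in genes of the exocrine pancreas, a set chosen after its values were seen. The SD of its log2 ratios was 0.66, against 0.32 to 0.39 on the other arrays. Amy2a5, a pancreatic amylase, had 3.99 on array 2 and between -0.42 and 0.44 elsewhere. The carboxypeptidase gene Cpb1 had 2.87, and Prss3, Reg2 and Reg1 had 2.55, 2.35 and 1.97. The mean of 22 such genes was 1.09 on array 2 and between 0.01 and 0.21 on the others.

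**Figure D4:**
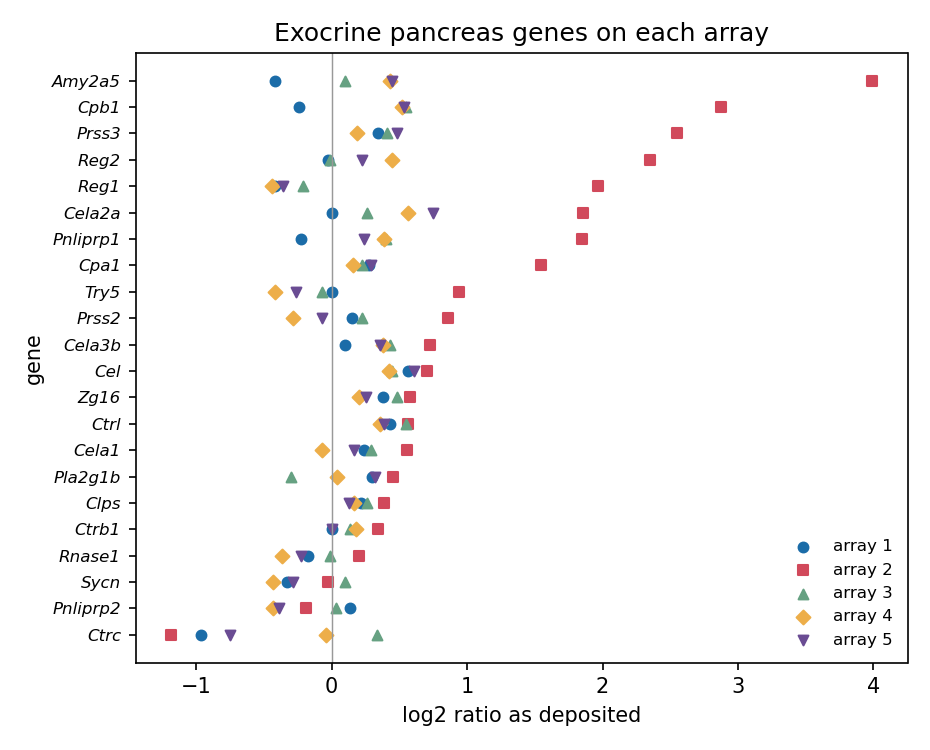
Log2 ratio as deposited (horizontal axis) of 22 exocrine pancreas genes, with 1 symbol per array. On array 2, 15 of the 22 genes lie at 0.5 or above and Amy2a5 reaches 3.99.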

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

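Among 120 series of 5 values (named genes, gene list means, summaries of the arrays and the mean of exocrine pancreas genes), 7 had 1 array far from the other 4. Chance gives about 1 in 20. The pancreas mean is 1 of the 7 and was chosen because its value on array 2 stood out, so it does not bear on that comparison. The tests on pancreas genes below were chosen after the result was seen.

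Zfp771 had -0.97 on array 3 and -2.30 to -2.02 on the others. Fas, a death receptor gene, had -0.53 on array 4 and -0.25 to -0.16 on the others. Relative to all features, the list of tumour necrosis factor and TRAF signalling had a mean of 0.18 on array 2 and -0.09 to -0.06 on the others. The mean subtracted was lower on array 2. There the subtraction moved 13 medullary epithelium genes from -0.07 to 0.14, against 0.18 to 0.22 on array 1. The value of 0.18 therefore does not show that these signalling genes had positive log2 ratios on array 2. The list of dendritic cells and MHC class II had 0.26 on array 3 and -0.01 to 0.03 on the others. The median of array 2 was -0.0841, against -0.01 to 0 for the others. Its SD was 0.66, against 0.32 to 0.39. The spots of a gene on array 2 nevertheless lay close together, with a median SD of 0.09 over 48 genes with at least 10 spots.

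The 22 exocrine pancreas genes had a mean of 1.09 on array 2 and of 0.01 to 0.21 on the others. More medullary epithelium, which makes proteins of many tissues, in 1 of the 2 thymuses would raise its own markers with them, but the median of 13 such markers was -0.0566 on array 2. That lay below the 0.71 of the pancreas genes (two-sided permutation test, p = 0.00605). The pancreas genes were chosen for their values on array 2, so this p-value is too small, and the marker median alone bears on the account. Pancreas RNA in 1 channel may account for the pattern, since Amy2a5, Cpb1 and Prss3 lay at 3.99, 2.87 and 2.55, yet 7 of the 22 genes lay under 0.5, among them Ctrb1 (0.34), Clps (0.39) and Ctrc (-1.19). None of the 22 is held by another list tested here, and how many of them the thymus itself makes was not analysed here. Without spot brightness, a probe that hardly binds cannot be told apart from a transcript that is not there, so this stays open. The liver genes Mup5 (2.93) and Alb (1.93) and the salivary amylase Amy1 (2.09) were high on array 2 too, but were picked from their sets. The median of 18 liver genes was 0.40 on array 2 and 0.04 to 0.25 on the others, with Apoa1 at -0.24 on array 2. The median of 6 salivary genes was 0.32 on array 2, within the 0.20 to 0.37 of the others, with Prol1 at -0.62. A difference between the 2 animals was not tested.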

How the results depend on the processing

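The position corrections, deposited numbers, named genes only, and all settings of the corrected values were chosen after seeing the data. The targeted gene stayed without a call, with means of 0.06 to 0.24 over its 14 alternatives. The count of changed genes, 4095 as deposited, ran from 734 to 4763 with 1 array left out, and was 6231 with array weights, 308 with a 1.5-fold mean added, 481 with local medians and 473 with column and row medians. Its other alternatives stayed within 1.5 times. Positive calls were 1973 of 4095 as deposited and 101 of 481 with local medians. With deposited numbers 3940 genes were called, 968 of them among the 4095. The genes past the 1.5-fold rule numbered 143, and 219 to 393 with 1 array left out (3 of 4 arrays needed), 12 at 2-fold, 26 with all 5 arrays needed, 40 and 36 with the 2 corrections, and 459 with deposited numbers, where names fall on the very low spots. The number of lists was 0, 0 to 1 with 1 array left out (cell cycle without array 3, adjusted p = 0.0306) and 1 with local medians.

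After local-median correction, the 481 genes became 23 to 1152 with 1 array left out and 2899 with array weights. The 40 genes past the 1.5-fold rule after position correction became 45 to 144 with 1 array left out and 384 with deposited numbers. The 1 list became 0 to 6 with 1 array left out, 8 with array weights, 8 with ranks, and 0 with column and row medians, deposited numbers or an estimated correlation. The median agreement of 0.66 became 0.49 with Spearman, 0.47 without the very low spots, and 0.46 with correction besides.

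Of 77 named genes other than Hivep3, 38 lost their call with local medians and 40 with column and row medians. The gene Tnfrsf4 turned to -0.0613 with local medians, and with column and row medians the gene Icam1 turned to -0.0114 and the gene Csf2 to -0.0203. Without array 5, 36 lost their call, and without array 4, 26. Of all 78, 33 passed in every left-out fit as deposited, and 8 after correction. The cause of these changes was not tested, except that the position corrections remove the shared trend and a left-out array leaves fewer arrays. Signal over background was not available as values here.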

Other observations

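The genes in this part were picked after their values were seen. The tests of position, cell cycle and cell types, and those of corrected values, were chosen after the results were seen. Some genes of the adipocyte list stood out on arrays 4 and 5. After position correction Ucp1, the heat-producing uncoupler of brown fat, had 1.32 and 1.18 on those arrays and -0.80 to 0.16 on arrays 1 to 3. Cox8b had 1.10 and 1.08, Cidec 1.09 and 1.39, and Car3 1.18 and 1.12. None of the 4 passed over the 5 arrays. Cidea and Elovl3, which also mark brown fat, had 0.39 and 0.26 on array 4 and 0.10 and 0.25 on array 5, with 0.45 and 0.23 on array 2. Scd1, a fatty acid desaturase on the same list, went the other way, at -0.57 (limma adjusted p = 0.012; negative on 5 of 5 arrays).

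Of the 7 lymph node stroma genes, whose list did not pass, 4 were high on array 1 and low on array 2. Ccl19 had 1.21 on array 1 and -0.43 on array 2 after correction, Cxcl13 0.99 and -0.44, Glycam1 0.99 and -0.64, and Chst4 0.58 and -0.49. The other 3 did not show this, with 0.35 and 0.08 for Madcam1, 0.01 and -0.14 for Cr2, and 0.20 and 0.35 for Fcer2a. Of 12 genes of MHC class I and the immunoproteasome, 3 were negative past the threshold after correction and 0 positive. B2m had a corrected mean of -0.43 (limma adjusted p = 0.041), Psmb8 -0.48 (0.049) and Tap2 -0.37 (0.03), each negative on 5 of 5 arrays. Their list did not pass. Hba-a1, an alpha globin gene, had 2.18 on array 2 and -0.75 on array 5.

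Log2 ratios rose from left to right on all 5 arrays. Genes of different content in different columns would leave no slope between 2 probes of 1 gene. Yet in the mean of the 5 arrays that slope was 0.52 from the first to the last column (95% bootstrap interval over probe pairs 0.46 to 0.58). Uneven dye signal across the slide is a candidate explanation, since probes of olfactory, vomeronasal and trace amine receptors, which a thymus hardly uses, rose by 0.56 (0.52 to 0.61). The design has 1 group on every array, and no biological explanation was tested.

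After correction, cell cycle genes lay low (mean -0.16) while the receptor genes had medians of 0.04 to 0.21, above 0 on 5 of 5 arrays. Ratios that run lower for abundant RNA may account for both. Ribosomal and oxidative phosphorylation genes, which are abundant, had a mean of -0.09, and cell cycle genes lay 0.07 lower (difference -0.07; two-sided permutation test over genes, p = 0.0379), but on 4 of 5 arrays only, so this stays open. A lower share of thymocytes may account for it too. In the mean of the 5 arrays, 168 marker genes of 12 other cell types lay 0.19 above 51 thymocyte genes (two-sided permutation test over genes, p = 1e-05, the smallest it can give). That difference did not hold on array 2. There, relative to all features, the receptor, early and CD4+CD8+ thymocyte lists stood at 0.14, 0.22 and 0.22, above most of the 12 other lists. Those 12 lists lay further apart than shuffled genes (permutation test over genes, p = 0.0101), but the highest, lymph node stroma, exceeded the lowest, macrophages, on 4 of 5 arrays only. That a difference had to hold on all 5 arrays was required only after a first rule without it had ruled out both accounts. Genes of a list vary together, so these p-values are too small, and an effect of the genotype on proliferation was not tested apart from these.

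Turning the sign of arrays gives 16 patterns, too few for a share under 0.05. The real pattern gave 4095 genes and the highest other 0, and after correction 481 and 0, and in both cases 1 of 16 patterns reached the real count. A trend shared by the arrays gives the same result. For the 1.5-fold rule the real counts were 143 and, after correction, 40, with 90 and 31 as the highest others, again 1 of 16. For lists, 16 of 16 patterns reached the 0 lists as deposited, with 12 as the highest, and 14 of 16 reached the 1 list after correction, with 15 as the highest when arrays 2 and 3 were turned. Turning array 3 alone gave 13 and array 2 alone 12.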
